A study of Homo sapiens with 6 samples.

How the data were processed

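Gene expression was measured by RNA sequencing in primary human CD4+ T cells carrying 1 of 3 lentiviral short hairpin RNAs (shRNAs). NTC is a non-targeting control, and Sh3 and Sh5 are both directed at DDX39B, an RNA helicase also known as UAP56 that takes part in splicing and mRNA export. Cells of 2 donors were used and each donor gave 1 library per shRNA, so that 6 libraries fall into 3 groups of 2. According to the labels' protocols the cells grew in RPMI with 20% serum and 100 ng/ml of IL-2, were activated through CD3 and CD28 for 2 days, and were exposed to virus for 3 days. Selection with puromycin took 4 days and was followed by 1 day without it. Libraries came from poly-A RNA enriched from 1 ug of total RNA with the TruSeq RNA kit.

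Reads were demultiplexed with bcl2fastq 2.20 and aligned with STAR 2.5.2b to GRCh38, per the submitters' processing notes. The authors deposited 4 tables, each comparing Sh3 or Sh5 with NTC within 1 donor, and per the file headers they were made with GFOLD 1.1.4, a program that ranks genes between libraries without replicates. Each table has 50032 rows. Per the file headers the values used here are RPKM (reads per kilobase of exon, scaled to the library's total), 1 column for each library of the pair. The deposited tables also give a GFOLD value and a plain fold change, both on the log2 scale. The deposited E-FDR column, a false discovery rate of the p-value kind, is 1 throughout and was not used. The gene annotation, the read counting and any use of strand are not given in the sources used here, so reads of a gene and of an antisense or overlapping gene cannot be told apart. The NTC columns of the 2 tables of a donor were identical.

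The planned test needed read counts, which the files do not hold, and the fallback written for normalized values was used instead. RPKM multiplied by GENCODE 29 exon length and the header total gave whole reads, within 0.05 reads in all 6 libraries, for 76.3% of 10628 genes with under 200 reads in every library. The header totals ran from 167693902 to 239146090 per library. No counts were rebuilt, because the lengths used by the authors are known for part of the genes only.

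Of the rows, 521 on the Y chromosome or of XIST and TSIX, and 27 of genes that not everyone carries, were left out of all tables. Of the 49484 rows used, 98.6% matched GENCODE 29 (GRCh38) by gene identifier, and all coordinates come from that annotation. Genes with a mean RPKM of at least 1 over the 6 libraries were tested, 14966 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(RPKM + 1) with the donor as a block and the shRNA as the group, which leaves 2 residual degrees of freedom. The moderated variance used a trend with expression (prior degrees of freedom 6.77), and p-values were adjusted by the Benjamini-Hochberg method, with a gene called at an adjusted p below 0.05. The contrasts were the mean of Sh3 and Sh5 against NTC, each shRNA against NTC, and Sh3 against Sh5. A separate model with donor, knockdown and their interaction tested the donor difference. Fold changes are from log2(RPKM + 1), which pulls those of genes near 1 RPKM toward 0. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

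The donor of each library was read from the number in its title, and libraries with the same number were treated as pairs. Their deviations from the group means correlated across genes at 0.74 to 0.75 within donors, and the component with the most variance (47.0%) separated the donors. A batch shared by same-numbered libraries could give the same picture.

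Tested on simulated data with 14966 genes, 200 of them changed, the fit recovered, averaged over 5 runs, 80.8% of 1.25-fold and 99.9% of 1.5-fold changes for the mean of both shRNAs. Of 1.25-fold changes it recovered 61.8% for Sh3, 61.4% for Sh5 and 65.4% for Sh3 against Sh5. For the donor difference it recovered 0.9% of 1.25-fold, 70.3% of 1.5-fold and 99.5% of 2-fold changes. False calls made up 6.91% to 8.52% of the calls for the mean contrast and up to 11.9% for Sh3, above the nominal 5%. The noise was drawn independently for each gene from its moderated variance. Noise shared by the genes of a library was left out, so these rates may be too favourable.

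Before the data were examined, 37 gene lists were fixed (29 programmes and 8 sets of markers of other cells), and so was the rule for the genes named in the text. DDX39B, its paralog DDX39A, FOXP3 and IL7R are always named. For the mean effect, the 10 largest rises and 10 largest falls are named among called genes that moved the same way in all 4 donor and shRNA pairs, with mean RPKM of at least 1 and a gene symbol. Antigen receptor segments, clone names and pseudogenes were passed over. For the other contrasts it is 5 per direction with the same sign in both donors, and per list up to 4 called members with the smallest p, or up to 2 given as values where none was called. Not every gene that the rule names is printed, and any other gene in the text was chosen after its values were seen. The lists were tested with camera from limma at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, for lists with at least 5 measured genes. With an estimated correlation camera refers its statistic to the 2 residual degrees of freedom, so hardly any list could pass. For the Th2 list the estimate was -0.08, yet camera's unadjusted p went from 3.4e-04 to 0.065. These p-values therefore cannot tell whether correlation between genes undoes a call. The p-values were adjusted over the 29 lists tested.

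Effects of both shRNAs share the NTC library of a donor, so unchanged groups were simulated against shared controls in 100 draws. Noise was again drawn independently for each gene. Alternatives tried were another pseudocount, no filter, a stricter threshold, no donor block, fewer groups in the fit, both shRNAs as 1 group, and each library or donor left out. Chosen after seeing the data were 4 other scalings of the libraries and a constant variance prior.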

Results

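The series asks what happens to CD4+ T cells when the helicase DDX39B is knocked down, and its title places FOXP3, the lineage factor of regulatory T cells, at the centre of that question. The data are RPKM values of poly-A RNA from 6 libraries: NTC, Sh3 and Sh5 from the first donor, and the same 3 from the second donor. The header totals were 222458967, 217261409 and 167693902 for NTC, Sh3 and Sh5 of the first donor, and 239146090, 201910146 and 202947467 for those of the second. What unit these totals count is not stated. RPKM times GENCODE 29 exon length, summed over genes, came to 140% to 142% of the totals. Reads counted for more than 1 gene, totals in another unit, or exon lengths other than the authors' may each contribute and were not told apart. Between 14772 and 15136 genes per library reached 1 RPKM. At these depths 1 RPKM for a transcript of 1 kb corresponds to 168 to 239 of the counted units. By the same product mitochondrially encoded genes came to 7.12%, 8.68% and 6.24% of the total in NTC, Sh3 and Sh5 of the first donor, and 8.20%, 9.06% and 7.24% in the second.

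DDX39B (ENSG00000198563.13, chromosome 6, 31530219 to 31542448 on the minus strand, GRCh38) fell strongly with Sh3 and little with Sh5. Its RPKM was 85.4 in the first donor's NTC library, 28.1 with Sh3 and 77.0 with Sh5, and in the second donor 90.9, 35.3 and 69.6. Group means were 88.2 ± 3.90 for NTC, 31.7 ± 5.10 for Sh3 and 73.3 ± 5.22 for Sh5 (SD, n = 2). With Sh3 the log2 fold change was -1.46 (SE 0.10, adjusted p 3.9e-04), a level 0.365 times that of NTC. With Sh5 it was -0.26 (SE 0.10, adjusted p 0.12), lower than NTC in both donors but short of the threshold, and on 1 Sh5 library it was -0.44 (adjusted p 0.082) without the first donor's and -0.09 (adjusted p 0.52) without the second donor's. With all NTC and Sh5 libraries kept, the same -0.26 was called without either Sh3 library (adjusted p 0.029 both times) and with no Sh3 library in the fit (adjusted p 0.027), so the call turns on how the spread is estimated. The difference between the shRNAs passed its own test at -1.19 (SE 0.10, adjusted p 9.0e-04). The mean of both shRNAs was -0.86 (SE 0.08, adjusted p 1.4e-03). Each of the 4 knockdown libraries held less DDX39B RNA than its donor's NTC library. DDX39A (ENSG00000123136.14), the close paralog of DDX39B, stood at 29.8 ± 0.400 RPKM in NTC and 32.6 ± 1.22 in knockdown, and its log2 fold change of 0.13 (SE 0.05, adjusted p 0.13) was not called.

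FOXP3 (ENSG00000049768.14, chromosome X, 49250436 to 49264826 on the minus strand) fell with both shRNAs in both donors. Its RPKM was 19.0 with NTC, 10.5 with Sh3 and 12.5 with Sh5 in the first donor, and 19.8, 11.9 and 13.3 in the second, or 19.4 ± 0.614 in NTC, 11.2 ± 0.961 with Sh3 and 12.9 ± 0.555 with Sh5 (SD, n = 2). The mean log2 fold change was -0.65 (SE 0.05, adjusted p 9.9e-04), with -0.74 (SE 0.06, adjusted p 5.9e-04) for Sh3 and -0.56 (SE 0.06, adjusted p 3.9e-03) for Sh5. The Sh5 fall was -0.57 but not called without the first donor's Sh5 library (adjusted p 0.057). The falls with Sh3 and Sh5 were not called different (-0.19, SE 0.06, adjusted p 0.067). RPKM per gene cannot show whether introns were retained or which isoform fell. The end of FOXP3 overlaps that of CCDC22 on the other strand, whose change was 0.05.

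IL7R (ENSG00000168685.14), the receptor chain for IL-7, differed between the shRNAs. Its RPKM was 202, 257 and 172 with NTC, Sh3 and Sh5 in the first donor, and 354, 401 and 303 in the second. It rose with Sh3 by 0.26 (SE 0.07, adjusted p 0.029), stood at -0.22 (SE 0.07, adjusted p 0.069) with Sh5, and the difference of 0.49 was called (SE 0.07, adjusted p 3.4e-03). The rise rests on single libraries: it was not called without the first donor's NTC (0.22, adjusted p 0.22), its Sh3 (0.18, adjusted p 0.19) or the second donor's NTC (0.30, adjusted p 0.052). Without the first donor's Sh5 library the difference was 0.44 (adjusted p 0.051).

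**Figure D1:**
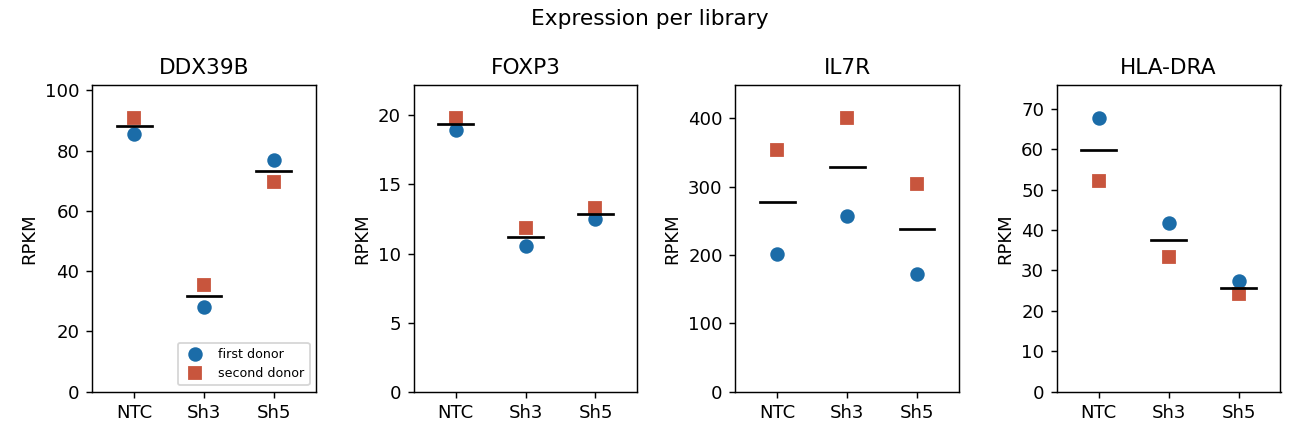
RPKM of DDX39B, FOXP3, IL7R and HLA-DRA in each library, by shRNA on the horizontal axis. Blue circles are the first donor, red squares the second, and black bars the mean of both; DDX39B lies at 28.1 and 35.3 RPKM with Sh3 but at 77.0 and 69.6 with Sh5, while FOXP3 lies at 10.5 to 13.3 RPKM in all 4 knockdown libraries and at 19.0 and 19.8 with NTC.

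The mean effect of the shRNAs asks what Sh3 and Sh5 change on average. It weighs both alike, although DDX39B was called lower with Sh3 and not with Sh5. The mean is thus not a measure of DDX39B loss alone. Many regulatory T cell, Th1 and interferon-stimulated genes fell, as did the type 2 cytokine genes IL5 and IL13 and the MHC class II genes HLA-DRA and HLA-DRB1, and the metallothionein genes MT1E and MT1F and JUN rose. In all, 1997 of 14966 genes were called, 965 higher and 1032 lower, with a median absolute log2 change of 0.29, so most changes were small. The split by direction depends on scaling: with the header constants it was 1409 higher and 677 lower. Of the called genes, 1855 moved the same way in all 4 donor and shRNA pairs (933 up, 922 down). The count rests on how the spread is estimated. Each donor gave 1 library per shRNA, so the spread is what remains after additive effects of donor and shRNA. With both shRNAs as 1 knockdown group limma called 0 genes (2261 at an unadjusted p under 0.05), and with no donor block 3. Without the first donor's NTC, without its Sh5 or without the second donor's NTC library it called 756, 1166 and 1317, and of the 108 named calls 50, 26 and 34 fell short, so changes of single genes in the lists are less certain than their p alone tells.

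The largest rise was that of BZRAP1 (now TSPOAP1; ENSG00000005379.15, chromosome 17, 58301228 to 58328760), from 4.29 ± 0.136 RPKM in NTC to 15.9 ± 5.21 in knockdown (log2 1.62, SE 0.07, adjusted p 9.2e-05). It overlaps the antisense gene BZRAP1-AS1, which changed by -0.33, so the 2 cannot be fully separated without strand. MBD6 rose by 0.79, DMPK, a kinase gene mutated in myotonic dystrophy, by 0.77, and PLXND1, a semaphorin receptor, by 0.76. MT1E (0.75) and MT1F (0.73) encode metallothioneins, which bind zinc and copper. JUN, an AP-1 subunit, rose by 0.67, the phosphodiesterase gene PDE1B by 0.65, the lysophosphatidic acid receptor gene LPAR2 by 0.63 and the lysozyme gene LYZ by 0.63. These 10 had SE of 0.06 to 0.09 and adjusted p of at most 2.7e-03. MBD6, DMPK, PDE1B and LYZ overlap genes on the opposite strand, and MT1E and MT1F share sequence with other metallothionein genes, so their levels are uncertain to that extent. Beside BZRAP1, 1 more called gene rose at least 2-fold: ENSG00000262202.4 (chromosome 17, 19112000 to 19112636), a long noncoding RNA known by a clone name and given here after its values were seen, at 1.28 (SE 0.07, adjusted p 2.6e-04). Its span holds SNORD3D, a copy of the U3 small nucleolar RNA, which has other near-identical copies, so its level is uncertain.

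The largest fall was that of IL13 (ENSG00000169194.9, chromosome 5, 132656263 to 132661110), a type 2 cytokine, with -1.26 (SE 0.26, adjusted p 0.018), the only called fall of at least 2-fold. Its RPKM was 1.04, 0.154 and 0.288 with NTC, Sh3 and Sh5 in the first donor and 7.91, 0.602 and 3.22 in the second, so the donors differed widely. Leaving out 1 library moved its change between -1.78 and -0.74, and it was not called without the first donor's Sh5 (adjusted p 0.093) or the second donor's Sh5 (adjusted p 0.057). IL5 on the same chromosome, the eosinophil growth factor, fell by 0.99 (SE 0.16, adjusted p 9.0e-03), and by 0.58 to 1.39 with 1 library left out, called each time. MZB1, an endoplasmic reticulum protein gene of B and plasma cells, changed by -0.93, the MHC class II genes HLA-DRB1 and HLA-DRA by -0.92 each, and DDX39B by -0.86. The immediate early gene EGR1 changed by -0.85, the interferon-induced IFI44L by -0.83 (SE 0.21, adjusted p 0.034), NT5E, which encodes the ectonucleotidase CD73, by -0.78 and the noncoding LINC00892 by -0.75. IFI44L ran from -1.42 to -0.25 with 1 library left out and was not called without the second donor's NTC (adjusted p 0.18), its Sh5 (adjusted p 0.12) or the first donor's Sh5 (adjusted p 0.084). For the named falls other than IL13, IL5 and IFI44L the adjusted p was at most 2.2e-03. IL13 and IL5 overlap genes on the opposite strand, and HLA-DRB1 has paralogs that differ between people.

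Genes of the regulatory T cell list fell together: 15 of 22 measured members fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.28. Besides FOXP3, the called members with the smallest p were CCR4, a skin-homing chemokine receptor (-0.56, from 114 RPKM in NTC), IL2RA, the high-affinity IL-2 receptor chain (-0.50), and GPR15, a gut-homing receptor (-0.41). The list was called by camera (adjusted p 3.6e-11) and not with an estimated correlation on 2 residual degrees of freedom (adjusted p 0.49), while fry gave 0.048. Of the 11 lists called by camera it is the only one that fry called; the other 10 had adjusted p of 0.053 to 0.21. Of all 29 lists fry called 3 in the mean effect, 6 with Sh3, 1 with Sh5 and 2 between the shRNAs. Of 13 genes listed as repressed by FOXP3, 3 fell and 0 rose (3 and 1 adjusted over the list alone), with a median of -0.04 (camera adjusted p 0.19, fry 0.048). Those that fell were IL5, IL13 and CD40LG (-0.35), the gene of CD40 ligand, which was not called without the first donor's NTC (-0.14, adjusted p 0.51) or its Sh5 (-0.30, adjusted p 0.11).

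The Th1, Th2 and Th17 lists were called lower by camera at its preset correlation and not with an estimated one. Of 20 Th1 genes 11 fell and 0 rose (14 and 1 adjusted over the list alone; median -0.41, camera adjusted p 2.1e-07, 0.49 with an estimated correlation). The IL-12 receptor gene IL12RB2 changed by -0.57, the chemokine gene CCL3 by -0.50 and the chemokine receptor gene CXCR3 by -0.42. Of 9 Th2 genes 4 fell and 0 rose (5 and 0 adjusted over the list alone; median -0.16, camera adjusted p 1.4e-03, 0.49 with an estimated correlation). They were IL13, IL5, the prostaglandin receptor gene PTGDR2 (-0.69) and the IL-25 receptor gene IL17RB (-0.51). Of 11 Th17 genes 3 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.19, camera adjusted p 9.1e-03, 0.59 with an estimated correlation), namely the transcription factor gene BATF (-0.39), the cathepsin gene CTSH (-0.34) and IL26 (-0.28). Camera did not call the Th17 list without the first donor's NTC (adjusted p 0.33) or its Sh5 (adjusted p 0.077). Of 5 follicular helper genes only CXCR5 passed, with a rise of 0.33 (2 rose and 2 fell adjusted over the list alone). The list's median was -0.07 and its mean 0.00 (camera adjusted p 0.96), which hid opposite shifts. Its median was -0.25 with Sh3 (fry adjusted p 4.3e-03) and 0.21 with Sh5 (fry adjusted p 3.2e-03). Fry also called the difference between the shRNAs (adjusted p 0.017). Camera called neither shRNA's shift (adjusted p 0.21 and 0.20).

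Interferon-stimulated genes fell as well: 17 of 39 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.25, camera adjusted p 2.8e-11, 0.59 with an estimated correlation). They included the guanylate-binding protein gene GBP1 (-0.52), PARP9 (-0.49) and the viral restriction factor gene BST2 (-0.49). Targets of IL-2 and STAT5, the signal of the cytokine in the medium, fell in 8 of 20 cases and rose in 0 (11 and 1 adjusted over the list alone; median -0.21, camera adjusted p 3.0e-04, 0.59 with an estimated correlation). Beside FOXP3 and IL2RA these were led by the feedback inhibitor gene SOCS3 (-0.59) and granzyme B, GZMB (-0.46). Of 12 inhibitory receptor genes 3 fell and 0 rose (6 and 1 adjusted over the list alone): LAG3 (-0.40), TIGIT (-0.27) and the ectonucleotidase gene ENTPD1 (-0.22). The list's median was -0.14 (camera adjusted p 5.7e-03, 0.49 with an estimated correlation). It was -0.24 with Sh3 (camera adjusted p 1.2e-03) and 0.01 with Sh5 (camera adjusted p 0.27). Camera did not call the list different between the shRNAs (adjusted p 0.093). ENTPD1 stood at -0.46 with Sh3 and 0.01 with Sh5, and TIGIT at -0.24 and -0.31.

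Proliferation lists were called in the same way. Of 30 mitotic genes 10 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.20, camera adjusted p 4.2e-05, 0.63 with an estimated correlation), among them the spindle genes TPX2 (-0.43) and NUSAP1 (-0.40) and the kinase genes BUB1 (-0.30) and AURKB (-0.23). Of 35 S phase genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.14, camera adjusted p 1.4e-03, 0.59 with an estimated correlation). The nucleotide synthesis genes TK1 (-0.54) and RRM2 (-0.43) fell, as did UHRF1, which maintains DNA methylation (-0.47). Sh5 carried the call of the S phase list (median -0.17, camera adjusted p 4.9e-07). With Sh3 alone camera did not call it (median -0.04, adjusted p 0.35). Of 13 measured replication-dependent histone genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.26, camera adjusted p 7.2e-03, 0.63 with an estimated correlation). HIST1H1C (-0.46), HIST1H3H (-0.36) and HIST1H2AC (-0.28) fell while HIST1H4C rose (0.59); these genes are near-identical copies whose messages mostly lack a poly-A tail. Camera did not call the histone list without the second donor's NTC (adjusted p 0.10) or its Sh5 (adjusted p 0.064). Of 12 nuclear long noncoding RNAs 4 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.14, camera adjusted p 3.7e-03, 0.49 with an estimated correlation): the paraspeckle RNA NEAT1 (-0.64), LINC00152 (now CYTOR, -0.29), PCBP1-AS1 (-0.28) and LINC00657 (now NORAD, -0.20).

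The other 18 lists, those of FOXP3-repressed and follicular helper genes included, were not called by camera. In the naive and central memory list of 17 genes, TXNIP (0.56), the lymph node egress receptor gene S1PR1 (0.37) and BACH2 (0.31) rose and NOSIP (-0.23) fell (5 and 2 adjusted over the list alone; adjusted p 0.39). Of 19 activation and early response genes 3 rose and 4 fell (4 and 7 adjusted over the list alone; adjusted p 0.23), with JUN and BTG2 (0.20) up and EGR1 and NFKBIA (-0.33) down. Of 26 T cell receptor signalling genes the phospholipase gene PLCG1 (0.23) and the kinase gene ZAP70 (0.24) rose and the adaptor gene LCP2 (-0.27) fell (1 and 1 adjusted over the list alone; adjusted p 0.37). Of 12 genes linked to autoimmunity 3 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p 0.57); TNFRSF1A, a TNF receptor gene, rose by 0.38, BACH2 rose, and FOXP3 and IL2RA fell. Of 15 genes flanking DDX39B 3 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p 0.19), and these were the cytokine genes LTB (-0.52), LTA (-0.44) and TNF (-0.59, SE 0.13, adjusted p 0.022). TNF ran from -0.92 to -0.25 with 1 library left out and was not called without the first donor's NTC (adjusted p 0.15), its Sh5 (adjusted p 0.095) or the second donor's Sh5 (adjusted p 0.059).

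Few RNA processing genes were called. Of 27 TREX and mRNA export genes DDX39B and the THO subunit gene THOC6 (-0.25) fell and MCM3AP (0.23) rose (2 and 1 adjusted over the list alone; camera adjusted p 0.45). Of 48 spliceosome genes 3 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p 0.071): DDX23 (0.31), AQR (0.24) and PRPF3 (0.22) rose and SNRPA (-0.22) fell. Of 47 splicing regulators 4 rose and 0 fell (3 and 0 adjusted over the list alone; adjusted p 0.061), namely CELF1 (0.29), HNRNPH1 (0.26), RBM5 (0.24) and RBM39 (0.19). Of 20 snoRNA host genes 5 fell and 0 rose (7 and 2 adjusted over the list alone; adjusted p 0.19), with SNHG3 (-0.42), LRRC75A-AS1 (now SNHG29, -0.37), SNHG19 (-0.32) and SNHG20 (-0.27) among the former.

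In the stress lists, 7 of 26 p53 targets rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p 0.19). PLK3 (0.31), SESN2 (0.30) and SESN1 (0.26) were up and CCNG1 (-0.32) was down. With Sh3 alone 3 rose and 2 fell (camera adjusted p 0.76). Sh5 alone gave 6 rises and 0 falls (camera adjusted p 0.027, 0.64 with an estimated correlation), so CCNG1 was not called lower with Sh5. Of 28 genes of the integrated stress and unfolded protein responses 3 rose and 6 fell (3 and 7 adjusted over the list alone; adjusted p 0.37); the falls included TRIB3 (-0.39), SHMT2 (-0.34), CEBPB (-0.33) and EDEM1 (-0.32). Of 19 heat shock genes BAG3 (0.21) and DNAJB1 (0.24) rose and HSPA8 (-0.23) and HSP90AB1 (-0.20) fell (3 and 4 adjusted over the list alone, adjusted p 0.42). DNAJB1 ran from 0.11 to 0.38 with 1 library left out. Of 22 DNA repair genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p 0.96), with TP53BP1 (0.29), AQR and FANCA (0.24) up and CHEK1 (-0.39) down. In metabolism, 2 of 24 cholesterol synthesis genes rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p 0.19, fry 0.048), with SREBF2 (-0.46) among the falls and INSIG1 (0.28) among the rises. Of 24 glycolysis genes 1 rose and 4 fell (2 and 6 adjusted over the list alone; adjusted p 0.18); PFKFB3 rose by 0.23, and EGLN3 (-0.34), TPI1 (-0.27) and GAPDH (-0.21) fell. Of 13 mitochondrially encoded genes 0 were called (0 also adjusted over the list alone; adjusted p 0.40), with MT-ND2 at 0.12 and MT-ND3 at 0.11. Genes in more than 1 list (such as FOXP3, IL2RA, IL5, IL13, LTA and TNF) are counted in each, so the lists are not independent.

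**Figure D2:**
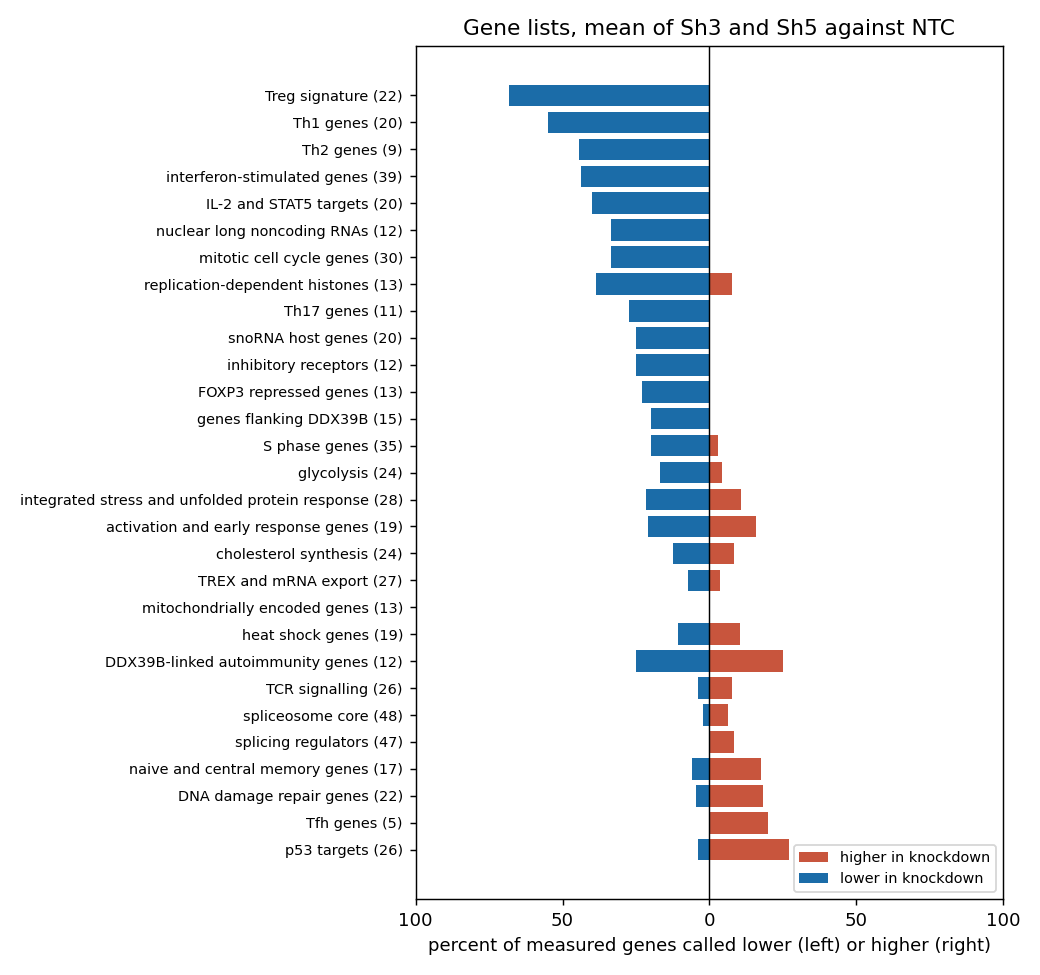
Percent of each list's measured genes (number in brackets) called lower (blue, left of 0) or higher (red, right of 0) in the mean of Sh3 and Sh5 against NTC. The regulatory T cell list has 15 of 22 genes called lower and 0 higher, the Th1 list 11 of 20 and 0, and the interferon list 17 of 39 and 0. Camera with an estimated correlation called 0 of the 29 lists, but on 2 residual degrees of freedom it could hardly call any.

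Markers of CD8 T cells, NK cells, dendritic cells, erythroid cells and platelets were low. The highest gamma-delta T cell, B cell and monocyte markers reached 10.1 to 16.2 RPKM. No CD8 T cell, NK cell, dendritic cell or erythroid marker reached a mean of 1 RPKM; the highest were CD8B (0.844), KLRF1 (0.329), LILRA4 (0.0358) and ALAS2 (0.112). Of the platelet markers TUBB1 reached 1.15 RPKM, with a change of -0.12 that was not called. Gamma-delta T cell genes reached 10.1 RPKM (TRDC), and 0 of 3 changed in the mean effect. Of the B cell markers CD79B (13.1 RPKM, -0.14, adjusted p 0.11) and CD79A (0.09, adjusted p 0.39) were not called in the mean effect. Of the monocyte markers LYZ (16.2 RPKM) rose by 0.63 and CD68 fell by 0.37.

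Sh3 alone asks what follows from the stronger loss of DDX39B RNA. It called 2765 genes, 1099 higher and 1666 lower, with a median absolute log2 change of 0.33, but with the header constants 1905 were higher and 1083 lower. The largest named rises were MT1F (1.24, from 4.36 to 11.7 RPKM), BZRAP1 (1.23), MT1E (0.96), DMPK (0.94) and JUN (0.91), with adjusted p of at most 4.7e-04. The largest falls were IL13 (-1.65, SE 0.30, adjusted p 9.1e-03), DDX39B (-1.46), IL5 (-1.23, SE 0.19, adjusted p 4.6e-03), EGR1 (-1.05) and the prostaglandin synthase gene PTGDS (-1.02, SE 0.09, adjusted p 6.5e-04), each lower in both donors. With 1 library left out IL13 ran from -2.37 to -0.93 and IL5 from -1.63 to -0.82, both called each time. Regulatory T cell genes fell in 16 of 22 cases (median -0.37, camera adjusted p 3.2e-09, 0.47 with an estimated correlation). Of 48 spliceosome genes 7 rose and 1 fell (camera adjusted p 2.1e-03, 0.68 with an estimated correlation), and of 13 mitochondrially encoded genes 5 rose (median 0.24, camera adjusted p 9.6e-05, 0.68 with an estimated correlation). Under the other scalings 0 (header constants), 1 (median-of-ratios factors), 1 (quantile) and 5 (without mitochondrial genes) of the 13 rose with Sh3. CD79B fell with Sh3 by 0.32 (adjusted p 9.2e-03), CD79A rose by 0.31 (adjusted p 0.030) and TRDC fell by 0.25 (adjusted p 0.024). Without the first donor's NTC, without its Sh3 or without the second donor's Sh3 library 1353, 1321 and 1672 genes were called, and without the donor block limma called 0 (2605 at an unadjusted p under 0.05).

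Sh5 alone asks the same of the shRNA that lowered DDX39B RNA less. It called 1392 genes, 770 higher and 622 lower, with a median absolute log2 change of 0.35. More were lower than higher with median-of-ratios factors (560 higher, 786 lower), after quantile normalization (516 and 610) and without mitochondrial genes (675 and 687). The largest named rises were BZRAP1 (2.01, SE 0.09, from 4.29 to 20.3 RPKM, adjusted p 5.0e-05), PLXND1 (1.31, SE 0.10), BTBD19 (0.86, SE 0.08), MBD6 (0.73) and PDE1B (0.71). The largest falls were HLA-DRA (-1.18, SE 0.07, from 59.9 to 25.7 RPKM), OST4 (-1.15, SE 0.08), a subunit gene of the N-glycosylation enzyme, and the cyclophilin gene PPIB (-1.09, SE 0.06, from 127 to 59.0 RPKM). SNX22 (-1.06, SE 0.06) and IFI44L (-0.95, SE 0.24, adjusted p 0.044) followed. IFI44L ran from -1.53 to -0.36 with 1 library left out and was not called without the second donor's NTC (adjusted p 0.061), its Sh5 (adjusted p 0.24) or the first donor's Sh5 (adjusted p 0.17). Without the first donor's Sh5 library BTBD19 (adjusted p 0.058) and PDE1B (adjusted p 0.069) were not called. PPIB and SNX22 overlap on opposite strands of chromosome 15, and OST4 overlaps AGBL5, so their levels may share reads. Regulatory T cell genes fell in 9 of 22 cases (median -0.18, camera adjusted p 3.3e-08, 0.58 with an estimated correlation) and interferon-stimulated genes in 12 of 39 (median -0.23, camera adjusted p 3.1e-10, 0.58 with an estimated correlation). Of 35 S phase genes 10 fell and 1 rose (camera adjusted p 4.9e-07, 0.58 with an estimated correlation). The first donor's Sh5 library, which had the lowest total, decides this count: without it 29 genes were called, without the second donor's Sh5 library 721, without the first donor's NTC 915, and with no donor block 4.

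Sh3 against Sh5 asks whether shRNAs against 1 target had the same effect. They did not: 2541 genes were called, 816 higher and 1725 lower with Sh3. More were lower under each scaling, but by less: 917 higher and 1034 lower with the header constants, 1067 and 1325 with median-of-ratios factors. The largest named differences upward were PPIB (1.08), the thromboxane receptor gene TBXA2R (1.07), SNX22 (1.06), MT1F (1.02) and the metallothionein gene MT2A (0.92). Downward they were DDX39B (-1.19), PLXND1 (-1.10), MYCBP (-1.07), the cholesterol exporter gene ABCG1 (-0.93) and SREBF2 (-0.92), the master regulator gene of cholesterol synthesis. These 10 had SE of 0.06 to 0.11 and adjusted p of at most 1.7e-03. All 13 mitochondrially encoded genes were higher with Sh3 (median 0.38, camera adjusted p 7.2e-10, 0.75 with an estimated correlation). With median-of-ratios factors and without mitochondrial genes in the scaling 13 were also called, with the header constants 5 and after quantile normalization 0. Also higher were 8 of 48 spliceosome and 8 of 35 S phase genes (camera adjusted p 4.4e-03 and 3.9e-03, 0.83 with an estimated correlation for both). Nuclear long noncoding RNAs were lower with Sh3 in 5 of 12 cases (camera adjusted p 0.010, 0.75 with an estimated correlation). The difference also took in CD79A (0.44), CD79B (-0.38) and LYZ (0.41). Of 3 gamma-delta T cell genes TRDC (-0.21) and TRGC2 (-0.32) were lower with Sh3 (adjusted p 0.045 for both; 3 lower adjusted over the list alone, median -0.29). Without the first donor's Sh3, without its Sh5 or without the second donor's Sh5 library 844, 664 and 1329 genes were called, and without the donor block limma called 0 (2452 at an unadjusted p under 0.05).

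Despite these differences the shRNAs overlapped. They called 287 genes higher in common and 277 lower, where independent lists of these sizes would share 56.5 and 69.2. In opposite directions they called 18 (up with Sh3) and 19 (down with Sh3), where independent lists would share 45.7 and 85.7. Simulated unchanged groups against shared controls shared at most 1 call in 100 draws. Those groups held no effects, so almost no gene was called in them, and this count cannot serve as a benchmark for the overlap. The counts for independent lists take no account of the shared NTC libraries either. Of all genes 39.9% had 1 sign in all 4 pairs, against 22.2% simulated. Across genes, which are not independent replicates, the log2 effects of Sh3 and Sh5 correlated at 0.47 and 0.52 within the donors, against 0.50 simulated from the shared NTC alone, but with covariances of 0.0226 and 0.0199 against 0.0062. Across donors, where no library is shared, Sh3 and Sh5 correlated at 0.22 and 0.40, Sh3 with itself at 0.68 and Sh5 with itself at 0.58. The NTC library of a donor cannot be split, so part of the overlap of calls may come from the shared controls. The same NTC shRNA is also the reference in both donors. Any effect of its own would add to the correlations across donors and to the shared signs.

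**Figure D3:**
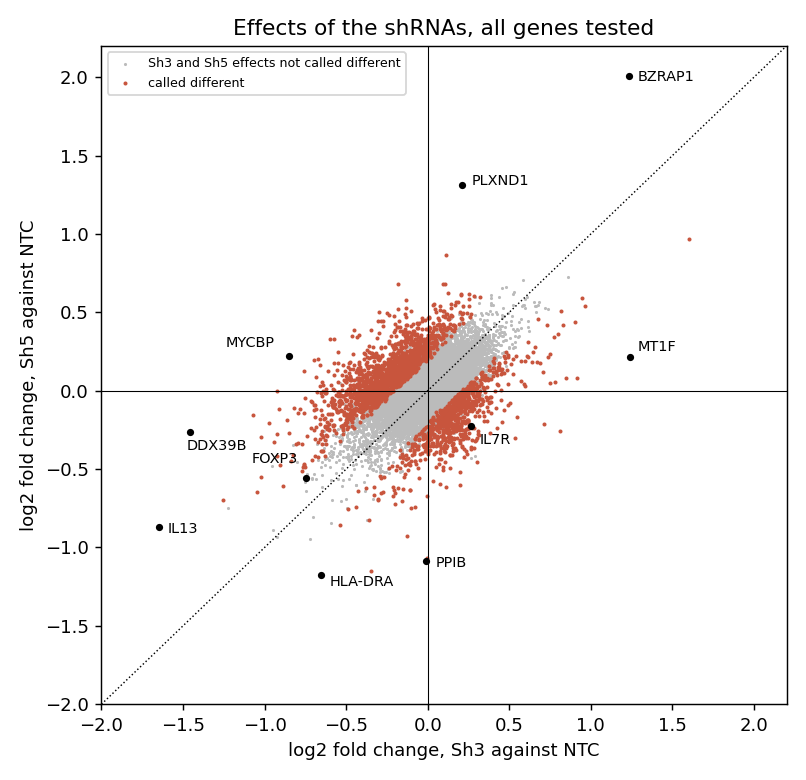
Log2 fold change of each of 14966 genes with Sh3 (horizontal axis) and Sh5 (vertical axis) against NTC. Red points are the genes called different between the shRNAs, grey the others, black the labelled genes, and the dotted line marks equal effects; DDX39B lies at -1.46 with Sh3 and -0.26 with Sh5, FOXP3 at -0.74 and -0.56.

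Whether the knockdown effect differed between the donors could be tested only roughly, with Sh3 and Sh5 as 2 knockdown libraries per donor. limma called 0 of 14966 genes (160 at an unadjusted p under 0.05). For DDX39B the difference was 0.00 (SE 0.82) and for FOXP3 0.06 (SE 0.21), both with an adjusted p of 1.00. Simulated differences of 2-fold were recovered in 99.5% of cases, but those simulations held no difference between the shRNAs, which here adds to the spread.

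In the authors' deposited tables, which compare single libraries, GFOLD gave DDX39B -1.45 and -1.31 for Sh3 in the first and second donor, and -0.10 and -0.35 for Sh5. The authors' FOXP3 values were -0.68 and -0.67 for Sh3 and -0.53 and -0.52 for Sh5. A GFOLD value of 1 sign in all 4 comparisons was given for 3759 genes, 2761 above 0 and 998 below. The authors' log2 values also hold the normalization constants of the file headers, which raise the first donor's Sh3 comparison by 0.12 over the RPKM ratio and the others by at most 0.02.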

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

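The tests of a mislabelled library, of fewer B cells or monocytes and of library scaling were chosen only after the result was seen. A test that Sh3 and Sh5 differ picked out each result in this paragraph, while the second pattern below was chosen from genes seen in the mean effect. It called 2541 genes, and 37 of them were called in opposite directions by the shRNAs. By Sh3 minus Sh5 on the log2 scale the named genes were DDX39B at -1.19, PLXND1 at -1.10, MYCBP at -1.07, ABCG1 at -0.93 and SREBF2 at -0.92, and on the other side PPIB at 1.08, TBXA2R at 1.07, SNX22 at 1.06, MT1F at 1.02, MT2A at 0.92 and IL7R at 0.49. The 13 mitochondrially encoded genes had a median of 0.38.

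The first pattern is that Sh5 called 1392 genes although DDX39B RNA fell far less with it. If Sh5 acted only as a weaker dose of Sh3, and each gene responded in proportion, gene effects would correlate near 1. Freed of noise by covariances between donors, they correlated at 0.498. An effect of the NTC shRNA, the reference in both donors, would still enter this value. The bootstrap interval over genes, 0.479 to 0.517, is too narrow since genes are not independent. The donor pairings taken singly gave estimates of 0.352 and 0.644. Removing trends on GC content and exon length from each library left 1844 Sh5 calls, which included 1287 of the 1392, and the Sh5 effects of the donors, which share no library, correlated at 0.576 (0.560 to 0.593), which a wrong label in 1 library would lower. These values argue against a weaker dose with proportional effects as the whole cause, GC or length bias and a single mislabelled library. A weaker dose to which genes respond out of proportion was not tested. Effects of a hairpin on other transcripts, and a DDX39B protein level that differs from the RNA level, stay open as hypotheses, since neither hairpin sequences nor protein were examined.

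The second pattern is that 10 of 10 MHC class II genes fell (median -0.61), a set put together after HLA-DRA and HLA-DRB1 were seen, and fell more with Sh5 (median -0.74) than with Sh3 (-0.47), opposite to the loss of DDX39B RNA. Fewer B cells or monocytes in the knockdown cultures would lower their markers alike, but of those at 5 RPKM or more in NTC CD79B changed by -0.14 and LYZ by 0.63, and the lowest bound of their intervals was -0.254. Only 2 markers could be used, MZB1, a gene of B and plasma cells outside the marker lists, fell by 0.93 from 3.03 RPKM in NTC, T cells may make both RNAs themselves, CD68 fell by 0.37 at a lower level and CD79B by 0.32 with Sh3, where CD79A rose by 0.31, so a part of the fall from such cells is not excluded. Under each of the 4 other scalings 10 of the genes were lower. As a hypothesis found in the same data, the T cells' own class II expression may have fallen, and the transactivator gene CIITA at -0.16 (adjusted p 0.15) was not called.

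The third pattern is the mitochondrially encoded genes, all 13 higher with Sh3 than with Sh5. Under the 3 other scalings that leave the highest ranks free the median difference was at least 0.409 (0.286 to 0.571 in single donors). Scaling without mitochondrial genes can only widen a mitochondrial excess. The median-of-ratios factors and header constants divided Sh3 by a smaller factor than Sh5 in both donors. None of the 3 could thus lower the difference, so they cannot decide whether scaling contributes to it. A first form of this test, replaced after its values were seen, counted calls and would have left scaling as an explanation: 5 of 13 were left under the header constants, where the median rose to 0.44 but the SE went from 0.083 to 0.125 and so ended the calls, and 0 under quantile normalization, which sets these top-ranked genes equal by construction. If unspliced transcripts were spared when DDX39B falls, nuclear single-exon genes would also be higher with Sh3. The 188 such genes instead lay at -0.049 relative to matched multi-exon genes, below rather than above the matched draws. The criterion fixed beforehand for rejecting this explanation asked for a value within 95% of the draws, so it was not met as written. Nuclear single-exon messages still depend on mRNA export, in which DDX39B also takes part, and the draws were matched on expression only. The comparison therefore cannot decide whether mitochondrial RNAs were spared. The share of mitochondrial transcripts may differ for reasons of cell state or RNA handling that the design cannot separate from the shRNA.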

How the results depend on the processing

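The tests of other scalings and of a constant variance prior were chosen only after the result was seen. Pairing by donor carries the calls: with no replicate block the counts were 3 for the mean effect, 0 for Sh3, 4 for Sh5 and 0 for Sh3 against Sh5, since donor differences then enter the spread. It left DDX39B at -0.86 (adjusted p 0.12) and FOXP3 at -0.65 (adjusted p 0.10), and of 138 named calls 132 fell short. With no filter on low values limma's 4 counts were 0 of 37218 genes (5353 to 6751 at an unadjusted p under 0.05) and all 138 fell short; the prior degrees of freedom went from 6.77 to 1.92 and the adjustment covered more genes, which was not separated, with DDX39B at -0.86 and FOXP3 at -0.65 (adjusted p 0.17 for both). With both shRNAs as 1 knockdown group and the replicate block 0 genes were called, DDX39B at -0.86 (adjusted p 0.36) and FOXP3 at -0.65 (adjusted p 0.11). At an adjusted p below 0.01 the counts were 378, 827, 203 and 744.

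Leaving out the first donor left 1 call for the mean effect and leaving out the second left 0 (831 and 678 at an unadjusted p under 0.05), on 3 libraries, with DDX39B at -0.86 both times (adjusted p 0.75 and 1.00) and FOXP3 at -0.62 and -0.68 (adjusted p 0.44 and 0.54). Leaving out 1 library gave 756 to 2037 calls for the mean effect, 1321 to 3259 for Sh3, 29 to 1971 for Sh5 and 664 to 3074 for Sh3 against Sh5, where a lone library is assumed to vary like the others. DDX39B then ran from -0.95 to -0.77 and FOXP3 from -0.68 to -0.62, both called each time (adjusted p 0.012 at most). The libraries that moved a count by over 1.5 times are those named with each comparison, and the first donor's Sh5 library moved it most (29 Sh5 calls). With the 2 compared groups alone and the block, 3249, 1956 and 3070 genes were called for Sh3, Sh5 and Sh3 against Sh5, and DDX39B with Sh5 passed (adjusted p 0.027).

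Scaling moved directions more than counts. With the header constants 1409 genes were higher and 677 lower in the mean effect (main 965 and 1032), 1905 and 1083 with Sh3 (1099 and 1666), 805 and 445 with Sh5 (770 and 622), and 917 and 1034 between the shRNAs (816 and 1725). That last split was 1067 and 1325 with median-of-ratios factors, 987 and 1148 after quantile normalization and 1012 and 1359 without mitochondrial genes, and with median-of-ratios factors Sh5 gave 560 and 786. Whether more genes rose or fell against NTC is thus not settled, while between the shRNAs more were lower with Sh3 under all 5 scalings. No named call changed direction while called, but leaving out 1 library ended many of the 138: 51 without the first donor's NTC, 36 without the second donor's NTC, 30 and 14 without their Sh5 and 10 and 11 without their Sh3. The donor difference stayed at 0 limma calls under each alternative run (118 to 1972 at an unadjusted p under 0.05).

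Of the 29 lists 11 were called, 10 to 14 with other libraries, scalings or no block, and 0 with an estimated correlation. That last form of camera rests on 2 residual degrees of freedom and could hardly call any list. The cross-donor correlation of Sh3 and Sh5 effects (mean 0.31) ran from 0.29 to 0.33. Alternatives planned for counts (DESeq2's size factors and test, a filter on mean count, prior counts and CPM) were not run.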

Other observations

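Genes of the cytosolic ribosomal proteins, a family looked at after values were seen, set the shRNAs apart. Of 77 measured, 16 rose and 2 fell with Sh3 (median 0.14), while 0 rose and 44 fell with Sh5 (median -0.28; 13 to 48 fell under the other scalings). Between the shRNAs 65 were higher and 1 lower with Sh3 (median 0.42), and 55 to 67 were higher under the other scalings, with the same direction of the median. The mitochondrially encoded genes moved the same way (8.68% and 9.06% of the total with Sh3, 6.24% and 7.24% with Sh5), so a difference in cell state or RNA quality is not separated from the shRNA here. Many of the ribosomal genes have processed pseudogenes that share their reads. The 4 measured metallothionein genes rose in the mean effect (median 0.61) under all 5 scalings, and with Sh5 alone 1 of them was called higher, and under 3 of the other scalings 1 was also called lower.

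The fall of MHC class II genes was the larger with Sh5, and 6 of the 10 were called higher with Sh3 than with Sh5. It took in the invariant chain CD74 (-0.50, from 209 RPKM in NTC), the peptide-loading genes HLA-DMA (-0.50) and HLA-DMB (-0.42), and HLA-DQA1 (-0.72), HLA-DQB1 (-0.70), HLA-DPB1 (-0.59), HLA-DPA1 (-0.44) and HLA-DOA (-0.62). These genes are polymorphic, so RPKM against 1 reference differs between people, but each comparison was within donors. Of genes outside the class II set, looked at after values were seen, IRF1 (-0.35, adjusted p 7.0e-03) and the class I peptide transporter gene TAP1 (-0.42, adjusted p 9.0e-03) fell. IFNG (-0.22, adjusted p 0.11) was not called.

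Of the 188 single-exon nuclear genes 8 rose and 30 fell with Sh3, with a median of -0.08 where matched multi-exon genes had -0.01. With Sh5 17 rose and 12 fell, with a median of 0.04 against 0.03, within the matched draws.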
